A study of Mus musculus with 20 samples.

How the data were processed

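Per the labels' protocols, HSCs were sorted as lineage-negative cells positive for cKit, Sca1 and CD150 and negative for CD48. RNA libraries were made from 3 to 5 ng of total RNA with a SMARTer Ultra Low kit, and ATAC libraries from 10000 sorted HSCs with Nextera transposase. The 20 samples comprise 6 RNA and 6 ATAC libraries, analysed here, and 8 samples of chromatin immunoprecipitation and input, not analysed here. The labels give mm10 for all of them.

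The deposited RNA files hold raw read counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, STAR 2.0.4, Subread featureCounts 1.4.5, HTSeq 0.8.0 and Partek 6.6 were used for RNA, with no roles given. The closing lines of each file carry the names that HTSeq writes for unassigned reads. They were left out of library sizes and tests. The share of reads assigned to genes was 17.25% to 17.49% in Control and 16.46% to 19.73% in Kdm6b-KO. Reads without a feature made up 30.38% to 40.78% and reads without a unique alignment 37.57% to 46.82% of each file. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping and antisense genes may be mixed. Of 49671 gene IDs, 49326 matched a symbol. Positions came from a table of the GRCm38.p6 assembly, the assembly of mm10, matched by symbol, and covered 89.8% of the tested and 84.3% of the called genes.

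The deposited ATAC files hold 1 peak list per library. Per the submitters' processing notes, cutadapt 1.16, BWA 0.7.16a and MACS2 were used, with no MACS2 version given. In each list the authors' fold enrichment is a ratio and the p and q are given as −log10 values. The values are each peak's own and were used here only to rank or filter peaks within a list and to describe single peaks. The smallest −log10 q in any list was 2.00. Read depth of the ATAC libraries is unknown here, and the number of peaks called moves with it. No list had 2 entries with the same start and end, so counting such entries once changed nothing.

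Groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, robust glmQLFit and glmQLFTest on genotype alone, two-sided, with Benjamini-Hochberg adjustment over 15185 tested genes and a threshold of 0.05. Log2 fold changes are Kdm6b-KO over Control, and their SE was taken as the size of the log2 fold change divided by the square root of the F statistic. CPM use TMM-scaled library sizes. The TMM factors ranged from 0.894 to 1.06. Where a group held 10 counts or fewer, the ratio of summed counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Lists of at least 4 measured genes, 26 of the 27, were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Replicate libraries were compared by the chi-square of their counts per degree of freedom, which was 16.83 or more for every pair, so none was treated as a duplicate. On simulated counts for this comparison, 14756 genes were tested. In them 200 sampled genes were changed, and the whole heat-shock list was raised by 1 on the log2 scale. Of the sampled genes, 36% of those changed by 1 on the log2 scale and 96% of those changed by 2 were recovered. Of all 152 calls, 9.87% were unchanged genes, more than the share of 0.05 aimed at.

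Genes to name were drawn from Kdm6b and Kdm6a, then the 10 called genes with the largest positive and the 10 with the largest negative log2 fold change among those with a mean of at least 5 CPM, no overlap between the groups' values and a symbol that is not a predicted-gene or pseudogene name, and then from each list up to 2 called members per direction or, with none called, its 2 members of highest mean CPM. Ppp1r15a, Egr1, Zfp36, Rrm2, Ccne2, Ms4a2, Cpa3 and Nlrp1a were chosen after their values were seen. So were Slc3a2, Asns, Atf4, Rsad2, Klrb1c, Tsix and Hbb-bt, named because they passed adjusted over their list alone.

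For ATAC, peaks of the 6 lists that overlapped by at least 1 bp were merged into regions, and a region was counted in a library when that library had a peak in it. On simulated lists the code recovered all 232 regions planted in the libraries titled 6bKO and all 123 planted in Control. Group means of peak numbers were compared with an exact permutation test and the similarity of lists with the Jaccard index in base pairs over the 10 splits of the 6 libraries. Genes were linked to regions within 50 kb of the annotated gene span, and named genes to peaks within 1 kb of either end, because the table of positions gives no strand. The design had named the transcription start site, so this is a departure from it. Tests of shares used Fisher's exact test in scipy 1.17.1. The planned motif search was not run, as it needs a genome sequence not used here. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 50 counts in at least 3 libraries, an adjusted p under 0.10, a replicate block and each library left out in turn. For ATAC they were a −log10 q of at least 5, equal numbers of top peaks, 50% coverage of a region, autosomes and distances of 5 and 100 kb. Leaving out the genes of chromosome 11 was added after the data were seen.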

Results

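Hematopoietic stem cells (HSCs) were sorted from mouse bone marrow to compare animals lacking Kdm6b in the blood system with controls carrying the same Cre driver. Kdm6b encodes a demethylase of histone H3 lysine 27, and the Vav driver expresses Cre recombinase throughout hematopoiesis. RNA was counted per gene in 3 Control and 3 Kdm6b-KO libraries, each from the pooled marrow of 3 male and 3 female mice aged 8 weeks and labelled as a biological replicate. Open chromatin was mapped by ATAC-seq, which marks accessible DNA by transposon insertion, in 3 libraries titled Control and 3 titled 6bKO. For ATAC the genotype label reads wild-type in all 6 libraries, so the groups were taken from the titles and are called the libraries titled 6bKO throughout. The other 8 of the 20 samples, from histone chromatin immunoprecipitation and its input, were not analysed here. Counts assigned to genes ranged from 6793873 to 13797890 in the Control libraries and from 8683106 to 19336121 in the Kdm6b-KO libraries, so that 3 counts corresponded to between 0.155 and 0.442 CPM (counts scaled to library size). Kdm6b-KO replicate 3 was the deepest library and had 22025 detected genes, against 25971 and 27316 in the other Kdm6b-KO libraries.

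The targeted gene was examined first. Kdm6b (chromosome 11, 69398508 to 69420367, GRCm38/mm10) had 198.3 ± 97.2 CPM in Control and 178.6 ± 31.8 CPM in Kdm6b-KO (SD, n = 3 each), a log2 fold change of -0.15 (SE 0.35, adjusted p = 0.882). The Control libraries held 92.0, 282.5 and 220.6 CPM and the Kdm6b-KO libraries 142.5, 202.1 and 191.3 CPM, so the groups overlapped. These are whole-gene counts that may include exons outside the deleted part, and the deleted exons are not given in the sources used here. The count therefore does not decide whether the labels are right. Kdm6a, the X-linked paralog with the same enzymatic activity, had 83.8 ± 2.56 CPM in Control and 71.7 ± 7.89 CPM in Kdm6b-KO (log2 fold change -0.23, SE 0.18, adjusted p = 0.590), and it did not pass the test.

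The comparison of Kdm6b-KO with Control HSCs asked which transcripts differ when the demethylase is lost in unperturbed mice. Immediate-early transcripts were among the genes with the largest increases. Fos, a subunit of the AP-1 transcription factor (chromosome 12, 85473890 to 85477274), rose 12.6-fold, from 8.30 ± 5.99 to 101.0 ± 33.2 CPM (SD, n = 3 each), with a log2 fold change of 3.65 (SE 0.50, adjusted p = 0.0323). Its paralog Fosb (chromosome 7, 19302696 to 19310118) rose from 1.93 ± 0.675 to 10.5 ± 3.85 CPM (log2 fold change 2.48, SE 0.43, adjusted p = 0.0142). Dusp1, a phosphatase that acts on MAP kinases (chromosome 17, 26505591 to 26508472), rose from 10.7 ± 3.65 to 46.6 ± 15.9 CPM (log2 fold change 2.12, SE 0.31, adjusted p = 0.00650). Ppp1r15a, a stress-induced phosphatase subunit, rose from 44.6 ± 10.9 to 95.2 ± 17.4 CPM (log2 fold change 1.09, SE 0.22, adjusted p = 0.0439).

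These 4 were the called members among the 32 measured genes of the immediate-early list, and the other 28 did not pass. Of the 32 genes, 26 had a positive log2 fold change, with a median of 0.73. The list as a whole was higher in Kdm6b-KO by camera with a preset correlation (adjusted p = 4.55e-08) and was not called with an estimated correlation (adjusted p = 0.473 with an estimated correlation). Adjusted over the list alone, 14 genes were higher and 0 lower. Among these were Egr1, at 24.5 ± 13.1 CPM in Control and 85.7 ± 35.0 CPM in Kdm6b-KO (adjusted p = 0.134 over all genes), and Zfp36, a factor that binds AU-rich messages for decay, at 66.1 ± 36.0 and 266.5 ± 87.0 CPM (adjusted p = 0.0754 over all genes). Egr1 had an adjusted p of 0.0240 without Control replicate 1, and Zfp36 of 0.00228 without Control replicate 3 and 0.0448 without Kdm6b-KO replicate 1, within ranges of 4.7e-11 to 0.376 and 2.73e-15 to 0.288. The calls of single members depended on individual libraries. Without Kdm6b-KO replicate 3, adjusted p was 0.0982 for Fos, 0.0581 for Fosb, 0.0516 for Dusp1 and 0.221 for Ppp1r15a, although the log2 fold changes of 3.75, 2.65, 2.19 and 1.14 were close to those of the full set. Without Kdm6b-KO replicate 2, adjusted p was 0.148 for Fosb, 0.0547 for Dusp1 and 0.243 for Ppp1r15a. Without Control replicate 2 it was 0.0935 for Fos and 0.159 for Ppp1r15a, and without Kdm6b-KO replicate 1 it was 0.0508 for Ppp1r15a. Over the 16 alternatives run, adjusted p ranged from 4.57e-37 to 0.0982 for Fos, from 4.51e-06 to 0.148 for Fosb, from 8.89e-12 to 0.0547 for Dusp1 and from 0.000279 to 0.243 for Ppp1r15a, which limma-voom did not call (adjusted p = 0.0587).

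**Figure D1:**
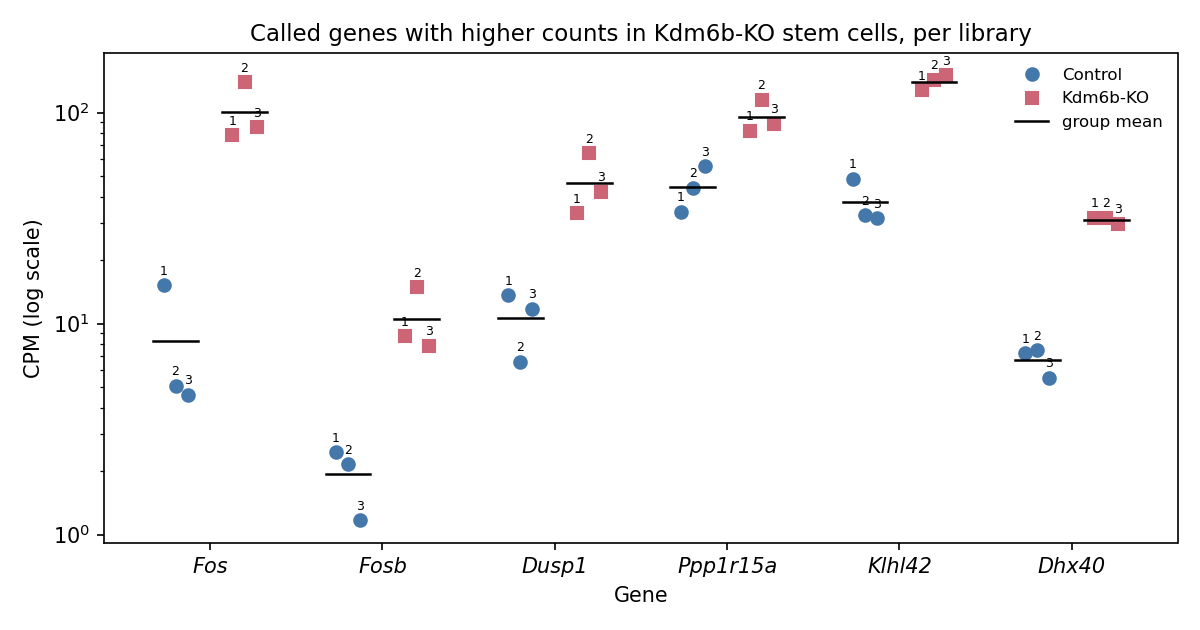
CPM on a log axis of 6 genes called higher in Kdm6b-KO, with 1 point per library numbered by replicate, circles for Control, squares for Kdm6b-KO and black lines for the group means. For each gene the 3 Kdm6b-KO points lie above the 3 Control points, as for Fos with 78.3, 139.2 and 85.5 CPM against 15.2, 5.08 and 4.60 CPM.

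Other named increases lay outside the immediate-early list. Klhl42, which encodes a substrate adaptor of a ubiquitin ligase (chromosome 6, 147090615 to 147112778), rose 3.74-fold, from 37.6 ± 9.50 to 140.2 ± 11.7 CPM (SE of the log2 fold change 0.21, adjusted p = 0.000429). The helicase gene Dhx40 (chromosome 11, 86768849 to 86807877) rose 4.63-fold, from 6.76 ± 1.05 to 31.1 ± 1.15 CPM (adjusted p = 0.000580). Ifi44l, an interferon-inducible gene on chromosome 3, had 2 counts in the 3 Control libraries together and 1008 in the 3 Kdm6b-KO libraries, a ratio of 346 with a 95% counting interval of 95.7 to 2860. Gbp2b, a guanylate-binding protein gene on the same chromosome, had 24 counts in the Control and 1008 in the Kdm6b-KO libraries together (log2 fold change 5.05, SE 0.50, adjusted p = 0.000429), and limma-voom did not call it (adjusted p = 0.0701, range over the alternatives 2.84e-32 to 0.0701). Nlrp1b, an inflammasome sensor gene, had 0.885 ± 0.548 and 12.4 ± 2.63 CPM (log2 fold change 3.76). Its neighbouring paralog Nlrp1a went the other way, from 4.64 ± 2.61 to 0.688 ± 0.220 CPM (log2 fold change -2.72, adjusted p = 0.0486). Reads of such near copies can be assigned to either, so these 2 values are uncertain, and the Nlrp1a call was lost without Control replicate 2 or 3 (adjusted p = 0.0935 and 0.157) and without Kdm6b-KO replicate 1, 2 or 3 (adjusted p = 0.0847, 0.224 and 0.239, range 0.000807 to 0.239), and under limma-voom (adjusted p = 0.0809). The remaining named increases were Aoc2 with a log2 fold change of 3.11 and Rapgefl1 with 2.43. Rapgefl1 had an adjusted p of 0.0516 without Kdm6b-KO replicate 3 (range 4.4e-08 to 0.0516).

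Among the decreases drawn by the naming rule, with a mean of at least 5 CPM, the largest was that of Med1. This gene encodes a subunit of the Mediator coactivator (chromosome 11, 98152154 to 98193313). It fell from 1227 ± 386 to 190.9 ± 26.1 CPM, 6.43-fold, with a log2 fold change of -2.68 (SE 0.27, adjusted p = 0.000209). Srsf2, a splicing factor gene (chromosome 11, 116849897 to 116853675), fell from 3269 ± 1675 to 734.1 ± 89.5 CPM (log2 fold change -2.15, SE 0.33, adjusted p = 0.00749). The adjacent Mettl23 had a log2 fold change of -1.87, Kpna2, an importin gene, -2.17, Cox11, a cytochrome oxidase assembly gene, -1.92, Stxbp4 -1.86, Lyrm7 -1.76 and Gid4 -1.38. Tnfsf13os had -2.24 and Ifit1bl1 -2.03, and both overlap other annotated genes, so that reads of the overlapping genes cannot be told apart without strand. Med1, Srsf2, Mettl23, Kpna2, Cox11, Stxbp4 and Gid4 likewise each overlap 1 other annotated gene and Lyrm7 overlaps 2. Without Kdm6b-KO replicate 3, adjusted p was 0.104 for Srsf2, 0.138 for Mettl23, 0.104 for Cox11, 0.269 for Lyrm7, 0.065 for Gid4, 0.105 for Tnfsf13os and 0.109 for Ifit1bl1. Without Kdm6b-KO replicate 2 it was 0.1 for Srsf2, 0.155 for Mettl23, 0.0797 for Cox11, 0.176 for Lyrm7, 0.0672 for Gid4, 0.107 for Tnfsf13os and 0.107 for Ifit1bl1. Med1, Stxbp4 and Kpna2 stayed below 0.05 with each library left out in turn. The losses from Control replicate 2, Lyrm7 at 0.159 and Ifit1bl1 at 0.0514, and from Kdm6b-KO replicate 1, Mettl23 at 0.0512, were fewer. Over the alternatives, adjusted p ranged from 7.25e-16 to 0.104 for Srsf2, 4.53e-12 to 0.155 for Mettl23, 2.57e-07 to 0.104 for Cox11, 0.000439 to 0.269 for Lyrm7, 1.51e-06 to 0.0672 for Gid4, 3.82e-06 to 0.107 for Tnfsf13os and 6.11e-06 to 0.109 for Ifit1bl1.

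In total, 70 of 15185 tested genes were called, 37 higher and 33 lower in Kdm6b-KO, by edgeR's quasi-likelihood test at an adjusted p under 0.05. An unadjusted p under 0.05 was found for 2254 genes, where chance would give 759. The groups did not overlap for any of the 70 called genes, nor for 20.5% of all tested genes, where chance gives 10%. Scaling by library totals gave a median log2 fold change of all genes of 0.147 and 70 higher and 30 lower genes, 70% against 52.9% higher in the main comparison. The count moved with single libraries. It was 519 without Control replicate 1 (187 higher, 332 lower), 46 without Control replicate 2 (27 and 19) and 161 without Control replicate 3 (80 and 81). Without Kdm6b-KO replicate 1 it was 97 (32 and 65), without replicate 2 it was 24 (16 and 8) and without replicate 3 it was 20 (13 and 7).

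The called genes were unevenly placed in the genome. Of the 59 called genes with a position, 27 lay on chromosome 11, the chromosome of Kdm6b, 45.8% of the calls against 8.22% of the tested genes (Fisher's exact test, odds ratio 9.63, adjusted p = 2.76e-13 over 20 chromosomes, with genes as units). None of the other 19 chromosomes passed, with adjusted p between 0.584 and 1. The 27 genes, 13 higher and 14 lower, lay between 40.7 and 121.4 Mb, and 13 of the 20 genes that the naming rule drew for their large changes were among them. With chromosome 11 genes left out, an alternative added after seeing the data, 19 genes were called, 12 higher and 7 lower, and Fos had an adjusted p of 0.0563 and Ppp1r15a one of 0.0688 at log2 fold changes of 3.66 and 1.10, against 3.65 and 1.09 with them.

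**Figure D2:**
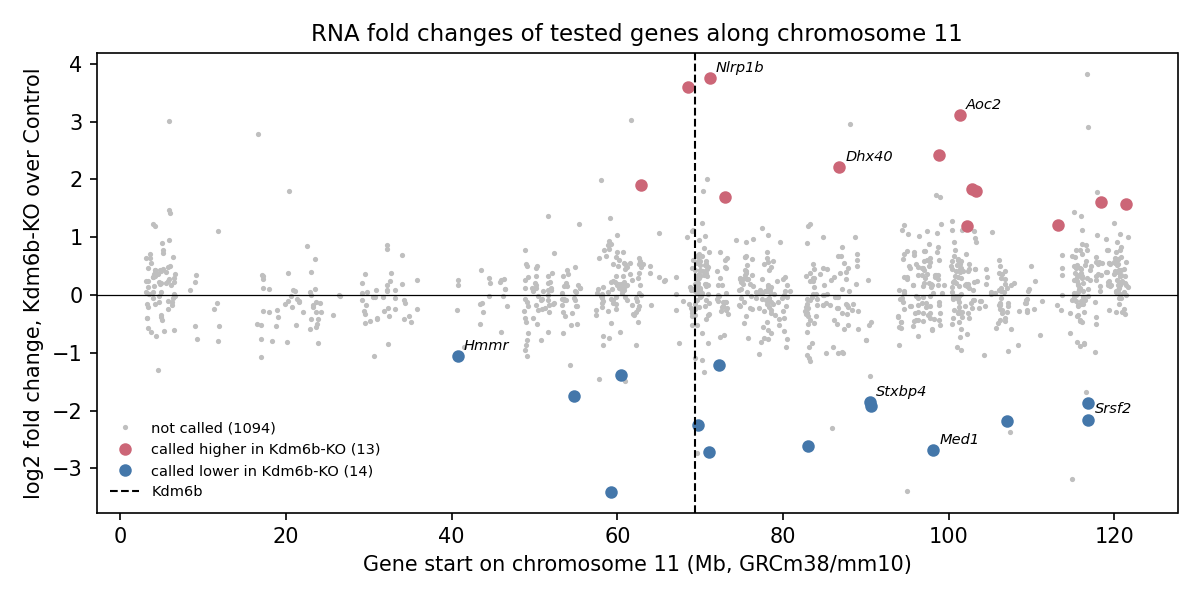
Log2 fold change (Kdm6b-KO over Control) of each tested gene of chromosome 11 against its start in Mb, with genes not called in grey, 13 called higher in red, 14 called lower in blue and Kdm6b as a dashed line. The called genes lie on both sides of Kdm6b, from 40.7 to 121.4 Mb, and in both directions.

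Proliferation genes were lower in Kdm6b-KO as a group with a preset correlation, although no single member passed over all genes. Of the 44 cell cycle genes measured, 35 had a negative and 9 a positive log2 fold change, with a median of -0.35. Camera called the list lower with a preset correlation (adjusted p = 8.41e-06), and the call was lost with an estimated correlation (adjusted p = 0.584 with an estimated correlation). The mean CPM of the cell cycle list was 183.5, 200.0 and 188.4 in Control and 146.2, 141.0 and 147.7 in Kdm6b-KO. That of the erythroid list was 760.1, 668.8 and 563.4 against 378.2, 306.1 and 384.6. The erythroid mean rested mainly on 1 of its 15 measured genes, Car2, at 9447 and 5098 CPM and not called over all genes. The next most abundant member, Car1, had 224.6 and 65.5 CPM. Adjusted over the cell cycle list alone, 8 genes were lower and 0 higher. They included Rrm2, a ribonucleotide reductase subunit, at 285.8 ± 39.4 CPM in Control and 149.7 ± 22.7 CPM in Kdm6b-KO, and Ccne2, a G1/S cyclin, at 93.9 ± 6.12 and 53.8 ± 1.26 CPM (SD, n = 3 each). Their adjusted p over all genes was 0.0591 and 0.0716, with ranges of 0.002 to 0.288 and 0.00602 to 0.301 over 16 alternatives, and 0.0155 and 0.0225 without Control replicate 1. Of the most abundant members, Cdk6 had 1713 ± 603 and 858.5 ± 92.2 CPM (adjusted p = 0.117) and Ccnd2 946.9 and 924.7 CPM (adjusted p = 0.960). The cell cycle inhibitor list was not called (adjusted p = 0.414), and its most abundant member Cdkn1b had 268.1 ± 128 and 97.4 ± 20.9 CPM (log2 fold change -1.46, adjusted p = 0.106). Cdkn1b had an adjusted p of 0.000534 without Control replicate 1 (range 1.5e-07 to 0.377), and Cdk6 one of 0.0385 (range 0.00359 to 0.409). Targets of p53 were higher as a list, with 16 of 20 positive, 0 called and a median log2 fold change of 0.37 (adjusted p = 0.0133, adjusted p = 0.473 with an estimated correlation). Their most abundant members Sesn1 and Rps27l had adjusted p of 0.493 and 0.515.

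Marker lists of 5 committed blood cell types were lower with a preset correlation, each lost with an estimated correlation (adjusted p = 0.584 to 0.633 with an estimated correlation), and the Kdm6b-KO libraries differed among themselves. The neutrophil and granulocyte list had 16 of 18 genes negative (median log2 fold change -0.47, camera adjusted p = 1.98e-05), the erythroid list 12 of 15 (median -0.84, adjusted p = 0.000360), the mast cell, basophil and eosinophil list 6 of 8 (median -1.13, adjusted p = 0.000133), the monocyte list 7 of 13 (median -0.29, adjusted p = 0.0351) and the B cell list 8 of 9 (median -0.43, adjusted p = 0.0368). The neutrophil median was -0.0186 without Control replicate 1, -0.81 without Control replicate 2 and -3.95, -0.00831 and 0.00115 without Kdm6b-KO replicates 1, 2 and 3. The erythroid median was -0.36 without Control replicate 3 and -0.44 without Kdm6b-KO replicate 2, and the mast cell, basophil and eosinophil median -4.27 without Kdm6b-KO replicate 1. With limma-voom the medians were -2.28 for the neutrophil, -2.12 for the mast cell, basophil and eosinophil, -1.08 for the B cell and -0.739 for the monocyte list. Mean CPM of the lists did not all follow the medians, at 8.40 in Control and 9.66 in Kdm6b-KO for the mast cell, basophil and eosinophil list and 35.8 and 36.6 for the monocyte list. In 4 of the 5 lists Kdm6b-KO replicate 1 lay above each Control library, with 262.2 CPM against at most 221.1 for neutrophil, 48.6 against 42.84 for monocyte, 29.1 against 23.52 for B cell and 26.43 against 14.44 for mast cell, basophil and eosinophil markers. With an estimated correlation the monocyte list had an adjusted p of 0.633 and the other 4 one of 0.584, and no member of these lists was called over all genes. Mpo, the granule peroxidase of myeloid cells (chromosome 11, 87793784 to 87804412), had 772.8, 356.9 and 547.0 CPM in Control but 1094, 55.9 and 20.3 CPM in Kdm6b-KO. Ngp, a neutrophil granule protein gene, had 1205, 323.8 and 601.1 CPM in Control and 1151, 27.7 and 26.9 CPM in Kdm6b-KO, and Car1, an erythroid carbonic anhydrase gene, 297.8, 154.9 and 221.2 against 169.2, 10.2 and 17.1 CPM. Without Kdm6b-KO replicate 1, adjusted p was 0.00963 for Mpo, 0.00633 for Ngp and 0.000129 for Car1, against 0.923, 0.878 and 0.588 with it and highest values over the alternatives of 0.999, 0.976 and 0.823. Car2, the paralog on chromosome 3, had 9447 ± 1422 CPM in Control and 5098 ± 580 CPM in Kdm6b-KO (log2 fold change -0.89, SE 0.26, adjusted p = 0.150). It passed adjusted over the erythroid list alone, where 1 gene was lower, Car2, and 1 higher, the erythroid marker Hbb-bt. Cpa3, a mast cell protease gene, had 14.2 ± 3.32 and 6.24 ± 1.41 CPM (adjusted p = 0.120) and was 1 of 3 genes lower adjusted over its list alone. Another, Ms4a2, had 66 counts in Control and 6 in Kdm6b-KO (ratio 0.0625, 95% counting interval 0.0221 to 0.143, adjusted p = 0.0526), with an adjusted p of 0.0486 without Control replicate 3 and 0.0428 without Kdm6b-KO replicate 1 (range 0.00144 to 0.308). The basophil and eosinophil markers Prg2 and Epx had adjusted p of 0.880 and 0.953, the monocyte markers Lyz2 and Ms4a6c 0.851 and 0.394, and the B cell markers Cd79b and Ighm 0.947 and 0.981. Adjusted over each list alone, 0 genes passed in the neutrophil, monocyte and B cell lists. The monocyte list had an adjusted p of 0.0652 and 0.165 without Control replicates 1 and 3 and 0.112 and 0.299 without Kdm6b-KO replicates 2 and 3, and the B cell list 0.0546, 0.165, 0.0659 and 0.292, within ranges of 0.000114 to 0.317 and 0.000483 to 0.292. The monocyte median was -0.0127 without Control replicate 3, -1.43 without Kdm6b-KO replicate 1 and -0.0895 without replicate 3, and 0.106 with the stricter filter (camera adjusted p = 0.317). The B cell median was -0.684 without Control replicate 2 and -1.55 and -0.214 without Kdm6b-KO replicates 1 and 3.

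**Figure D3:**
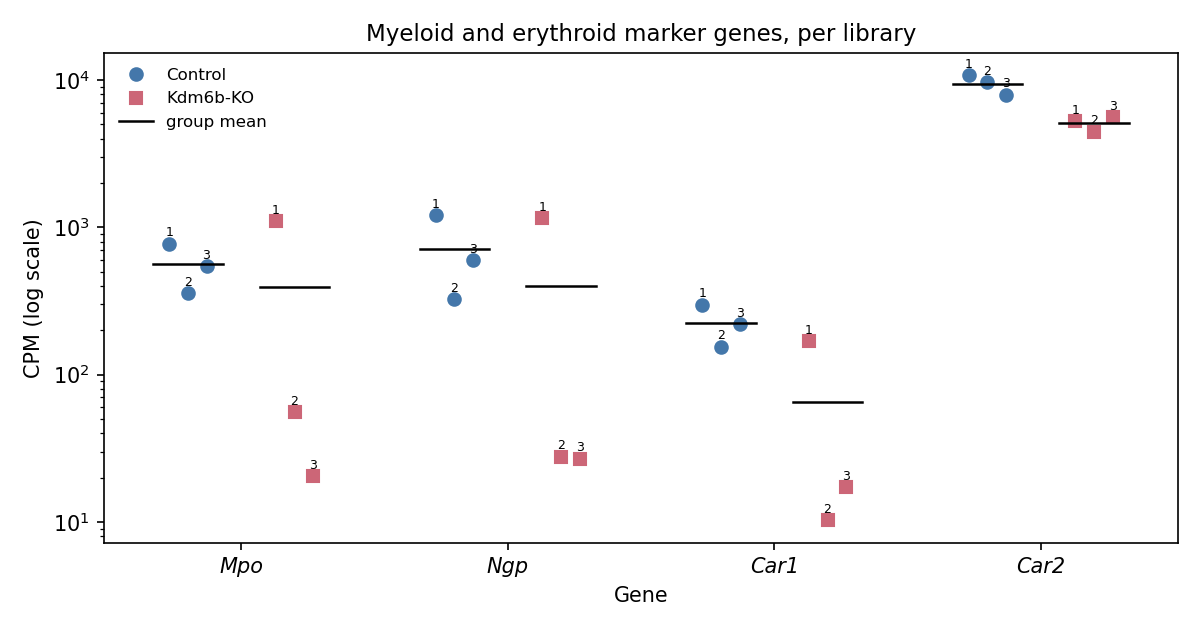
CPM on a log axis of the myeloid genes Mpo and Ngp and the erythroid-expressed genes Car1 and Car2, with 1 point per library numbered by replicate, circles for Control, squares for Kdm6b-KO and black lines for the group means. For Mpo, Kdm6b-KO replicate 1 lies at 1094 CPM, above the 3 Control libraries, while replicates 2 and 3 lie at 55.9 and 20.3 CPM.

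Stem cell identity genes were not called as a group. The list of 38 genes had 20 positive and 18 negative values (camera adjusted p = 0.509, 0 called). Kit, the stem cell factor receptor, had 1605 ± 730 and 995.0 ± 156 CPM (adjusted p = 0.343), with an adjusted p of 0.0257 without Control replicate 1 (range 0.0257 to 0.779). The H3K27 and H3K4 enzyme list had 31 genes and an adjusted p of 0.511, with 1 gene, Kmt2d, passing adjusted over the list alone at 1369 ± 619 and 620.3 ± 48.1 CPM (adjusted p = 0.105 over all genes, 0.0109 without Control replicate 1, range 0.000331 to 0.392). Kdm5a had 361.8 ± 60.8 and 359.1 ± 68.1 CPM. Of 39 Hox genes 10 were measurable (adjusted p = 0.859), with Hoxa9 at 75.8 ± 3.07 and 92.3 ± 22.0 CPM and Hoxa7 at 48.4 ± 5.07 and 60.1 ± 4.12 CPM. Of 46 developmental genes silenced by Polycomb in many cell types, 1 was measurable, Isl1, with 3.53 ± 1.48 and 2.68 ± 1.05 CPM, so that list was not tested.

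Interferon genes had 28 of 41 negative values (adjusted p = 0.0741). Xaf1, an interferon-inducible apoptosis factor gene, was called, from 69.8 ± 5.34 to 30.2 ± 2.82 CPM (log2 fold change -1.21, adjusted p = 0.00840). Xaf1 lies on chromosome 11 (72301461 to 72313733) and is among the 27 called genes placed there. The Xaf1 call was lost without Kdm6b-KO replicate 2 (adjusted p = 0.07) or 3 (adjusted p = 0.104, range 5.59e-06 to 0.104), and the interferon list had an adjusted p of 0.0446 without Control replicate 1 and 0.00903 without Kdm6b-KO replicate 3 (range 0.00903 to 0.302). Adjusted p was 0.762 for heat-shock genes, 0.174 for NF-kappaB targets, 0.174 for targets of the unfolded protein response and ATF4, 0.832 for the ETS family, 0.660 for adhesion and homing, 0.971 for cholesterol synthesis, 0.302 for ribosomal proteins and 0.414 for mitochondrially encoded genes. It was 0.302 for multipotent progenitor markers, 0.302 for megakaryocyte markers, 0.511 for T and NK cell markers, 0.578 for stroma and endothelium markers and 0.0534 for sex-linked genes. Of these lists, sex-linked genes had an adjusted p of 0.0155 without Control replicate 3 and 0.0384 and 0.00928 without Kdm6b-KO replicates 1 and 2 (range 0.00928 to 0.344). Ribosomal proteins had 0.000576 without Control replicate 1 and 0.0347 without Kdm6b-KO replicate 3 (range 0.000576 to 0.934), mitochondrially encoded genes 0.00860 without Kdm6b-KO replicate 1 (range 0.00860 to 0.881), and megakaryocyte markers 0.0337 without Kdm6b-KO replicate 2 (range 0.0337 to 0.938). Adjusted over the list alone, 3 genes of the unfolded protein response and ATF4 list were higher (Slc3a2, Asns and Atf4), 2 interferon genes lower (Rsad2 and Xaf1), 1 T and NK cell marker higher (Klrb1c) and 1 sex-linked gene lower (Tsix). Hsp90ab1 had 2521 ± 345 and 2417 ± 409 CPM, Hspa8 518.8 ± 22.7 and 389.4 ± 13.8, Nfkb1 183.9 ± 24.9 and 222.8 ± 35.2, Fli1 1773 ± 335 and 1089 ± 127, Cd34 332.4 ± 34.3 and 392.6 ± 73.0, and Vwf 71.8 ± 7.28 and 111.4 ± 69.1 CPM.

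The ATAC comparison asked whether open chromatin differs between the libraries titled 6bKO and Control. At Kdm6b itself a region of 384 bp inside the gene (chromosome 11, 69401233 to 69401616, mm10) held a deposited peak in 3 of 3 Control libraries and in 0 of 3 libraries titled 6bKO. Its −log10 q in the Control lists was 8.45, 8.57 and 62.9. The nearest regions on either side, at 69396721 to 69397263 and at 69408537 to 69409077, held peaks in all 6 libraries. The region is 1 of 431 found in each Control list and in none titled 6bKO. Whether it belongs to the deleted part of the gene is not given in the sources used here.

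**Figure D4:**
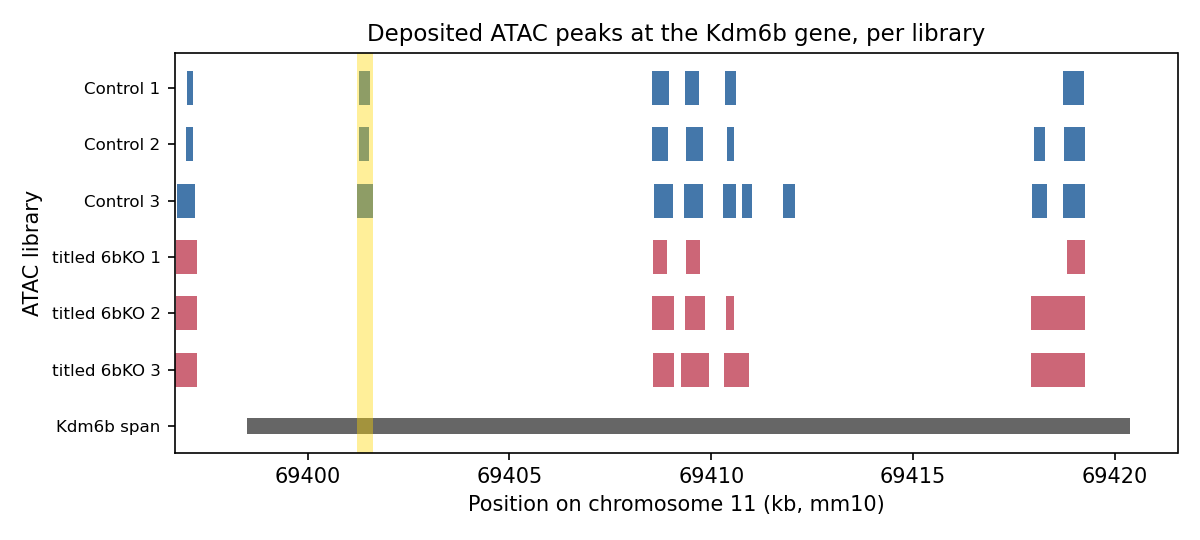
Deposited ATAC peaks (bars, to scale) in each of the 6 libraries along chromosome 11 in kb (mm10), Control in blue and titled 6bKO in red, above the annotated span of Kdm6b in grey. The region shaded in yellow, 69401233 to 69401616, has a bar in the 3 Control libraries and in none of the 3 titled 6bKO.

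Peaks at the ends of 3 myeloid and erythroid genes also separated the titles. Of 70 named genes with a position, 36 had a peak within 1 kb of an end of the gene in all 6 libraries, among them Fos, Dusp1, Med1, Srsf2 and Klhl42. Mpo, Ngp and Car1 each had such a peak in 3 of 3 Control libraries and in 0 of 3 titled 6bKO, and 0 named genes showed the reverse. Within the span of each of the 3 genes, titled 6bKO replicate 1 held 1 peak and replicates 2 and 3 held 0. Over all 21913 placed genes the balance ran the other way. There 17 had an end peak in each Control library and in none titled 6bKO, and 114 showed the reverse. Kdm6b had no peak within 1 kb of its annotated ends in any library. A region just outside that window, at 69417926 to 69419263 with the annotated end at 69420367, held peaks in all 6.

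The number of peaks and the similarity of the lists were compared next. Control libraries had 47450, 44739 and 62125 peaks and those titled 6bKO 63682, 53692 and 69729, means of 51438 ± 9350 and 62368 ± 8100 (SD, n = 3 each, two-sided exact permutation test, p = 0.2, where 0.1 is the smallest this design allows). Pairs of lists shared a mean Jaccard index of 0.387 within groups and 0.362 between groups, a difference of 0.0247 (one-sided exact test over 10 splits, p = 0.2). The 6 lists merged into 149774 regions, of which 19466 were in all 6 libraries and 89727 in 1 library. Each library titled 6bKO and no Control held 1948 regions, and each Control and no library titled 6bKO held 431. With equal numbers of top peaks these were 1486 and 731. The count toward the libraries titled 6bKO was 4579 without Control replicate 3, 5199 without titled 6bKO replicate 1 and 3665 without replicate 2. The count toward Control was 2289, 1170 and 701 without Control replicates 1, 2 and 3 and 1354 without titled 6bKO replicate 3. Chromosome 11 held 5.75% of the regions found toward the libraries titled 6bKO and 7.89% of those toward Control. Its share was 6.25% of all regions and 7.91% of the regions in all 6 libraries, close to the share toward Control.

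Group-specific regions were set beside the genes called in RNA. Within 50 kb, 12 of 35 placed higher genes, among them Fos, Rapgefl1 and Ifi44l, had a region specific to the libraries titled 6bKO, 34.3% against 15.9% of genes not called (Fisher's exact test, odds ratio 2.76, adjusted p = 0.0166 over 4 tests). Regions specific to Control lay within 50 kb of 6 of 35 higher genes, 17.1% against 4.98% (odds ratio 3.95, adjusted p = 0.0166), among them Nlrp1b and Rapgefl1. Of 24 placed lower genes, 8 had a region specific to the libraries titled 6bKO, 33.3% (odds ratio 2.65, adjusted p = 0.0573), a share close to that of the higher genes. Among them were Kpna2, Mettl23, Srsf2 and Xaf1, and 0 lower genes had a region specific to Control (adjusted p = 0.630). At 5 kb the first share was 11.4% (adjusted p = 0.380) and the second 14.3% (adjusted p = 0.00220), and at 100 kb both had an adjusted p of 0.0588. Genes are not independent replicates, and gene length was not adjusted for.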

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

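The tests of strain variants, of a local effect, of other cell types, of isolation stress, of the Kdm6b titles and of peak depth, and the splits of the RNA gene count and of the ATAC regions, were chosen only after the results they concern were seen. The share of ATAC peaks on chromosome X, which enters no comparison of the report, was 1.70%, 1.78% and 1.75% in the Control libraries and 2.97%, 2.12% and 2.18% in the libraries titled 6bKO, means of 1.74% and 2.42604% (exact permutation test, p = 0.1, the smallest this design allows). Chromosome Y held 25, 32 and 31 peaks in Control and 16, 28 and 20 in the libraries titled 6bKO (exact permutation test, p = 0.2). A peak within 1 kb of an end was found for Xist in 0 Control libraries and 2 titled 6bKO, and for Ddx3y in 3 and 1. The labels state pooled marrow of both sexes for the RNA libraries.

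Called RNA genes were concentrated on chromosome 11 with Kdm6b, 27 of 59 placed calls. A gain or loss of a chromosome segment was predicted to shift the median by at least 0.5. The median log2 fold change of all tested chromosome 11 genes was 0.0789 (95% interval 0.054 to 0.112). The bound written beforehand against a gain or loss, an interval within 0.1 of 0, was missed at its upper end. The reading that the shift lies far below 0.5 was adopted after the value was seen. This median covers all of chromosome 11. A shorter segment, or one in only some of the pooled mice, could leave it unmoved. A single gain or loss would shift the genes in it in the same direction. The 27 called genes were 13 higher and 14 lower, which argues against a single segment as the account of all 27. A segment behind part of them stays open. A local effect of the deletion needs called genes close by, and 7.41% of the 27 lay within 1 Mb of Kdm6b (95% interval 0.91% to 24.3%). Variants of another strain carried along with the targeted allele could account for it and were not tested directly. Genes not called within 30 Mb of Kdm6b had an unadjusted p under 0.05 more often than those of other chromosomes (18.8% against 14.1%, odds ratio 1.41, 95% interval 1.14 to 1.74). Other causes acting along this chromosome would give the same, so the odds ratio does not single out strain variants. The 30 Mb window was set after the positions of the called genes were seen, chromosome 19 alone had 18.9% of all its tested genes under 0.05, and an effect of Kdm6b loss on these genes stays open.

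Of 32 immediate-early genes 4 were called higher in the Kdm6b-KO libraries, and the list was called with a preset correlation but not with an estimated one (adjusted p = 0.473 with an estimated correlation) or with fry (adjusted p = 0.0771). Cells of another mature type in the sort would bring their own transcripts, and of 8 such marker lists 0 had a higher mean CPM in each Kdm6b-KO library than in each Control library. This count covers only cells present in every Kdm6b-KO library, and list means can rest on single abundant genes. It misses cells in single libraries: neutrophil markers had 262.2 CPM in Kdm6b-KO replicate 1 against at most 221.1 in Control. Stress during cell isolation might raise immediate-early genes as well, and cannot be told apart from genotype, since the labels give no sort day and heat-shock genes had a median log2 fold change of -0.147 with an interval of -0.311 to 0.444. An effect of Kdm6b loss on these genes was not tested separately.

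The ATAC libraries titled 6bKO carry a wild-type genotype label. Whether the titles or that label are right cannot be told apart here: 0 of 3 had a peak at the Kdm6b region, but the region was picked for that absence, so a mislabelled sample is not excluded. A peak caller threshold or shallow depth stays open for the same reason. Regions with a −log10 q of at least 8.45 in each Control library numbered 15484. Of these, 0.355% had no peak in any library titled 6bKO, which does not decide this question. The cutoff was the lowest Control value at the Kdm6b region. That region had 62.9 in Control replicate 3, so the 15484 were not matched to it in strength. A deletion of the region in these libraries stays open and was not tested.

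The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Each other split still sets most Control libraries against most libraries of the other group, so part of a group difference stays in it. Its counts are therefore not those of chance alone. For RNA genes called the real count was 70 and the highest other 1, so that 1 split gave as many. For gene lists called it was 8 and 9, and 3 splits gave as many. Of the 9 other splits, 5 called the immediate-early list (smallest adjusted p 0.00264, real 4.55e-08), 4 the cell cycle list (5.18e-08, real 8.41e-06), 0 the p53 list (0.174, real 0.0133), 4 the neutrophil list (2.01e-38, real 1.98e-05) and 4 the erythroid list (1.77e-10, real 0.000360). They called the mast cell, basophil and eosinophil list in 4 (5.64e-09, real 0.000133), the monocyte list in 3 (1.58e-10, real 0.0351) and the B cell list in 3 (1.19e-09, real 0.0368). For ATAC regions specific to a group it was 2379 and 2589, and 2 splits gave as many, the other setting Control replicate 3 and titled 6bKO replicates 2 and 3, against the rest.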

How the results depend on the processing

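Leaving out the genes of chromosome 11 was the only alternative chosen after seeing the data. For named genes other than Kdm6b, 808 results kept their direction and their side of the threshold, 43 passed it, 42 no longer did and 28 changed direction, and for gene lists 295, 13, 11 and 17 (direction by camera). RNA genes called were 430 with DESeq2's Wald test (180 higher, 250 lower), 576 without a low-count filter (249 and 327), 140 at an adjusted p under 0.10 (71 and 69) and 19 without genes of chromosome 11 (12 and 7), and the cause was not tested. The 19 were all among the 70. With library totals 70 were higher. With each library left out in turn they ranged from 20 to 519, from 13 to 187 higher and from 7 to 332 lower. With the replicate number as a replicate block, 88 were called (35 higher, 53 lower), 56 of them shared with the 70, the monocyte and B cell lists had adjusted p of 0.202 and 0.0888, and the neutrophil median was -2.13. Under the block, Nlrp1a and Lyrm7 were no longer called (adjusted p = 0.0676 and 0.0533), and 3 named genes not called before passed. Same-numbered libraries deviated together with correlations of 0.0324, 0.161 and -0.127, so the numbers do not pair them. Gene lists called were 8, and 5 with the stricter filter, 0 with an estimated correlation and 0 with fry, and 7 to 10 with each library left out. For ATAC, regions specific to Control were 731 with equal numbers of top peaks and those specific to the libraries titled 6bKO 1486, and leaving out each library gave 2200 to 5199 regions specific to the libraries titled 6bKO and 478 to 2289 specific to Control. The replicate block gave a similarity difference of 0.0383. The share of higher genes near a region specific to the libraries titled 6bKO was 11.4% at 5 kb and 42.9% at 100 kb, and near one specific to Control 20% at 100 kb. For lower genes near a region specific to Control it was 0% at 50 kb and 12.5% at 100 kb, not called at either distance. Changes of direction were all in genes and lists not called in either analysis. As log2 fold changes, library totals gave 0.00925 for Kdm6b, 0.0895 for Hsp90ab1, 0.12 for Ccnd2, 0.13 for Kdm5a, 0.11 for Cd79b and 0.00609 for Ighm, no filter 0.0152 for Kdm5a, limma-voom -0.42 for Prg2 and -2.06 for Epx, and the replicate block -0.93 for Epx. With each library left out in turn, values ranged from -0.49 to 0.19 for Kdm6b, -0.21 to 0.0483 for Hsp90ab1, -0.0984 to 0.0185 for Ccnd2, -0.15 to 0.13 for Kdm5a, -3.88 to 0.039 for Mpo, -0.0652 to 0.33 for Lyz2, -0.21 to 0.0838 for Cd79b, -2.25 to 0.49 for Ighm, -3.52 to 4.16 for Prg2 and -5.56 to 3.901 for Epx. List medians were -0.000885 (library totals) and -0.0593 (no filter) for heat shock, -0.0674 for Hox and -0.351 for T and NK cell genes (no filter), and -0.0339 (DESeq2 size factors) and -0.0289 (stricter filter) for cholesterol synthesis. With each library left out they ranged from -0.199 to 0.0136 for heat shock, -0.122 to 0.22 for Hox, -0.017 to 0.0776 for ETS, -0.148 to 0.0729 for cholesterol synthesis, -0.0493 to 0.289 for ribosomal and -0.497 to 0.208 for mitochondrial genes. The motif alternatives were not run. Depth limits genes near 0.155 to 0.442 CPM, the value of 3 counts.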

Other observations

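The count of genes by peaks at their ends was chosen only after the named genes were seen. Of 21913 placed genes, 17 (0.0776%) had a peak within 1 kb of an end in each Control library and in none titled 6bKO, and 114 (0.52%) the reverse. Among 19 neutrophil and granulocyte markers, 2, Mpo and Ngp, were of the first kind, and another choice of 3 libraries also gave 2. In RNA, Mpo had 1094, 55.9 and 20.3 CPM and Ngp 1151, 27.7 and 26.9 CPM in Kdm6b-KO replicates 1, 2 and 3. The RNA and ATAC libraries were separate samples.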
